A study of Homo sapiens with 6 samples.

How the data were processed

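Total RNA from HN5 cells was measured on 6 Illumina expression arrays, 3 of the erlotinib-sensitive parental line and 3 of its erlotinib-resistant derivative. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I, and labelled with biotin using the Ambion MessageAmp kit. The labels call the samples of each group biological replicates 1 to 3 but do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be partly technical. Groups and replicate numbers were taken from the sample titles. No slide, scan or batch information is given in the sources used here.

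The values analysed are the authors' normalized log2 signals, deposited as 1 value per probe and sample for 47230 probes. The software and its version, the background treatment and the normalization method are not given in the sources used here. The scale was read from the values: they ran from 6.51 to 13.76 on each array, with medians near 6.90, and base 2 was taken because another usual base would put the brightest probe far beyond the range of a scanner. The sorted values of the 6 arrays were nearly identical, as after quantile normalization, with a median difference of 0.00075 and a largest difference of 0.00434 between arrays at any rank. Such a normalization removes any difference in total signal between arrays, so each change is relative to the other probes of the same array. A table of signals before normalization was not used, because its 12 per-sample columns (6 of signal and 6 of detection) carry no name that ties them to a sample.

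Because of this, the planned normexp background correction of the raw signals was replaced by the authors' values, which had been listed as an alternative, and the planned filter on detection p-values by a limit set from the values themselves. On each array, background was described by the mode of the values and the SD of the values below it, and a probe counted as above background when it exceeded the mode by 3 SD, a limit of about 6.98. Between 40.7% and 40.8% of probes passed on each array. Probes above the limit on at least 3 of the 6 arrays were kept. Values near the floor are compressed, so fold changes on this scale understate the change of dim genes. Where every array of 1 group was at background, the change is given as at least N-fold, from the brighter group's mean log2 value to the dimmer group's mean of the background limits.

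Probes were named through the platform's annotation table: 30112 had 1 gene symbol, 8 had several and 17110 were not listed there and stay unnamed. For 30073 of the named probes the Entrez ID was found in the reference gene table, which changed 0 symbols. After the filter 15249 named probes were tested as 11375 genes, each gene being represented by its tested probe with the highest mean. Of the 3094 genes with more than 1 tested probe, 29 had probes called in opposite directions. No coordinates are given, because the files name no genome build.

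Resistant arrays were compared with parental arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a replicate block), on 4 residual and 8.91 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 3 tested members. The number of arrays limits the precision; the standard error of a log2 difference is given with the values.

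The comparison, the gene lists, the rule for naming genes and the alternatives to be tried were chosen before the data were examined. The markers of other cell types were to be reported as levels and detection only, and testing them as lists departs from that plan. The 21 lists were TAM receptors and ligands, ERBB receptors and ligands, other receptor tyrosine kinases and ligands, ERK output genes, mesenchymal genes, epithelial junction and identity genes, keratinocyte differentiation genes, basal keratinocyte genes, cell cycle genes, type I interferon response genes, NF-kB and inflammatory cytokine genes, cholesterol synthesis genes, NRF2 target genes, xenobiotic metabolism and drug transport genes, hypoxia and glycolysis genes, BCL2 family genes, stress response genes of the ATF4 and unfolded protein pathways, YAP target genes, and markers of fibroblasts, leukocytes and endothelial cells. The named genes are the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose probe was above background on all 3 arrays of the brighter group, 8 fixed receptor and ligand genes (AXL, GAS6, PROS1, MERTK, TYRO3, EGFR, ERBB2 and ERBB3), and up to 4 members of each list with the smallest adjusted p. Other list members are named as examples, chosen after their values were seen. The 8 gene families of the closing section were also chosen after the values were seen.

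Alternatives that were run were no filter, a stricter filter (5 SD on all 3 arrays of a group), the mean of a gene's probes, moderation with a trend and robust fit, array weights, the replicate number as a block, each array left out in turn, an adjusted p threshold of 0.01, a test against a fold of 1.2, camera with an estimated correlation, and fry. The strict filter's limit, cyclic loess on top of the authors' values, and subtraction of each array's background mode from linear values (with an offset of 16) were added after seeing the data.

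The fit was tested on data simulated around the mean signals of the 11375 genes, with 50 genes changed at each of 4 sizes. Variances were drawn from limma's fitted prior, and noise was normal and independent between genes, as the fit assumes. It recovered 48% of genes changed 1.2-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold. Among 183 calls 9 were of unchanged genes, and 0 genes were called when nothing had been changed. A list shifted on purpose was found, and 1 other list was called. The simulation changed far fewer genes than the 53% called in the data, so its recovery need not hold there. With independent genes it cannot show how the list test treats correlated members. Its few false calls follow partly from its construction.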

Results

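HN5 is a human head and neck squamous carcinoma cell line, and erlotinib is a small-molecule inhibitor of the kinase activity of the epidermal growth factor receptor (EGFR). The resistant line was derived from the parental line by raising erlotinib stepwise over 3 months to 12.5 µM and then holding it there for 6 months. Gene expression was measured on 3 parental and 3 resistant arrays as normalized log2 signal. Arrays of the same group correlated across probes at r = 0.9965 to 0.9970 (6 pairs), and arrays of different groups at r = 0.978 to 0.980 (9 pairs); probes are not independent replicates. The labels do not say whether erlotinib was in the medium at harvest, so the presence of the drug cannot be separated from the resistant state. All resistant arrays measured the same derived line. Effects of its months in culture, or changes peculiar to this line, cannot be separated from resistance either.

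The study asked which genes differ between parental and acquired-resistant HN5 cells, and its title names the receptor tyrosine kinase AXL. AXL rose 7.40-fold in the resistant cells, from 8.22 ± 0.231 to 11.11 ± 0.313 (mean log2 signal ± SD, n = 3 each). The difference was 2.89 on the log2 scale (SE 0.135, limma adjusted p = 1.29e-09), and both AXL probes rose, by 2.38 and 2.89. GAS6, the ligand of AXL, rose by 0.27 (SE 0.0641, limma adjusted p = 0.00314). PROS1, a ligand of the related receptors TYRO3 and MERTK, fell by 0.17 (limma adjusted p = 0.0324). That call was lost without parental replicate 1 or 3 or without any 1 of the resistant replicates, where the adjusted p lay between 0.0655 and 0.143, and with cyclic loess (0.0521); over all alternatives it lay between 0.0113 and 0.143. TYRO3 differed by -0.18 and did not pass (limma adjusted p = 0.0506). It passed without parental replicate 1 or 3 (adjusted p = 0.0211 and 0.0495), with the replicate block (0.0488), the strict filter, the mean of probes, the moderation trend or array weights, and the alternatives spanned 0.0211 to 0.233. MERTK was not tested, because neither of its probes was above background on enough arrays. Among the 4 tested TAM receptors and ligands, 2 rose and 1 fell over all genes, and 2 rose and 2 fell adjusted over the list alone. As a list they did not stand apart from other genes (camera adjusted p = 0.490).

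EGFR, the target of erlotinib, was bright in both groups, at 11.91 ± 0.0925 in parental and 11.75 ± 0.0693 in resistant cells (SD, n = 3 each). The difference of -0.15 did not pass the test (limma adjusted p = 0.0573). It passed without parental replicate 1 (adjusted p = 0.0250) and with the moderation trend or the replicate block, and the alternatives spanned 0.0250 to 0.438. The 4 EGFR probes ranged from -0.15 to 0.33, and 1 of them rose; their mean turned the difference to 0.05 (adjusted p = 0.438), so its direction depends on the probe. ERBB2 fell by 0.31 (SE 0.0570, limma adjusted p = 5.09e-04). ERBB3, the kinase-impaired partner receptor, fell by 0.31 (SE 0.0940, limma adjusted p = 0.0138), a call lost without parental replicate 1, parental replicate 2 or resistant replicate 2 (adjusted p = 0.0596, 0.0563 and 0.0753; 0.00283 to 0.0753 over all alternatives). Among ERBB ligands, HBEGF rose by 0.73 and BTC went from background to 6.99, at least 1.01-fold, while NRG4 fell by 0.81 and EREG fell by 0.37. With the background mode subtracted the folds of NRG4 and EREG went from 1.76 and 1.29 to 3.70 and 2.17. Of the 10 tested ERBB receptors and ligands 2 rose and 4 fell (3 and 5 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.539). The other receptor tyrosine kinases and ligands also went both ways, with 3 of 13 rising and 4 falling, the same counts adjusted over the list alone (camera adjusted p = 0.653). The insulin receptor adaptor IRS2 rose by 0.85, FGF2 by 0.40 and ROR1 by 0.39, and the collagen receptor DDR1 fell by 0.64. MET differed by -0.15 (limma adjusted p = 0.194).

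**Figure D1:**
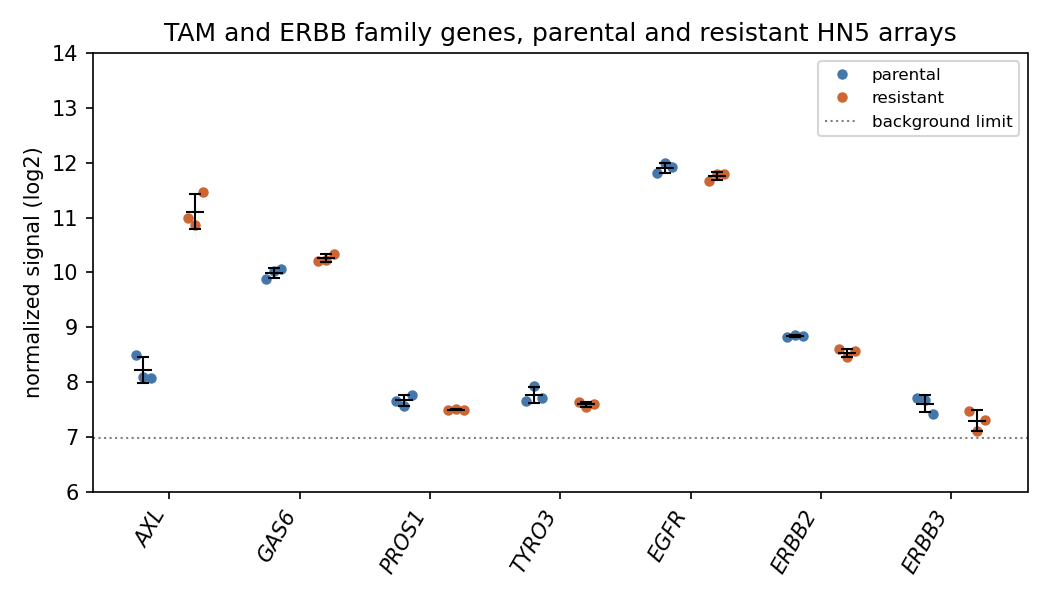
Normalized log2 signal of AXL, its relatives and ligands, and ERBB receptors in 3 parental and 3 resistant arrays; points are arrays, black marks the mean with 1 SD, and the dotted line is the background limit. AXL lies between 8.08 and 8.49 on the parental and between 10.87 and 11.46 on the resistant arrays, while the EGFR means are 11.91 and 11.75.

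The matrix metalloproteinase gene MMP7 rose 11.3-fold in the resistant cells, the largest rise as measured; genes at background in a group give only lower limits and cannot be ranked against it. CXCL8, which encodes the neutrophil chemokine interleukin 8, rose 9.92-fold, and the related chemokine gene CXCL1 rose 5.38-fold. PTGS2, the inducible cyclooxygenase, rose 6.57-fold, the mitochondrial superoxide dismutase gene SOD2 6.29-fold and the antiviral gene RSAD2 6.30-fold. ALPK2, CCL2, NNMT, COL6A3 and DCN were at background on all parental arrays and rose at least 7.88-fold, 7.35-fold, 6.23-fold, 6.47-fold and 5.54-fold; 2 other DCN probes reached 7.46 and 7.77, and the mean of its probes gave a fold of 2.78. With AXL these are the 12 largest rises as measured (log2 differences 2.43 to 3.50, limma adjusted p = 4.32e-13 to 1.29e-09).

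FABP4, a fatty acid binding protein, had the largest fall as measured, to a level 9.79-fold lower in resistant cells; genes that fell to background cannot be ranked against it. The matrix metalloproteinase genes MMP10 and MMP1 fell 5.91-fold and 5.02-fold, opposite to MMP7. The cell adhesion gene CNTNAP2 fell 5.85-fold, the carbonic anhydrase CA2 5.66-fold, SIRPA 5.63-fold, GTSF1 5.55-fold and KANK4 4.60-fold. LGALS7B, which encodes the keratinocyte lectin galectin-7, fell 6.47-fold, and its near-identical copy LGALS7 4.54-fold, so the copies cannot be told apart. The cancer-testis antigen genes MAGEA1 and CTAG2 and the centrosomal gene CEP15 reached background on all resistant arrays and fell at least 7.71-fold, 5.16-fold and 5.07-fold. Their other probes fell less, by 1.22, 0.30 and 0.41 on the log2 scale, and the mean of each gene's probes gave folds of 4.49, 2.72 and 2.74. The 12 largest measured falls had limma adjusted p = 5.56e-13 to 3.86e-10.

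Across the 11375 genes tested, 6029 (53%) changed, of which 2967 rose and 3062 fell (limma, Benjamini-Hochberg). Many changes were small: 1970 of the changed genes moved by under 1.2-fold, and 362 moved at least 2-fold, with 227 higher and 135 lower in resistant cells. In 33 of these 362 genes the other group was at background on all arrays, 23 of them among the rises and 10 among the falls. The parental and resistant arrays did not overlap for 6721 genes (59.1%, where chance gives 10%). Subtracting the background mode, chosen after seeing the data, raised the number changed at least 2-fold to 1006. It gave folds of 17.1 for MMP7, 12.9 for PTGS2, 26.0 for FABP4, 14.5 for LGALS7B, 15.7 for GTSF1, 10.4 for CA2, 9.86 for CNTNAP2, 9.001 for MMP1 and 7.19 for KANK4. For the 8 of the 24 largest measured rises and falls with a group at background it gave 28.7 to 49.5, values that depend on the offset.

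**Figure D2:**
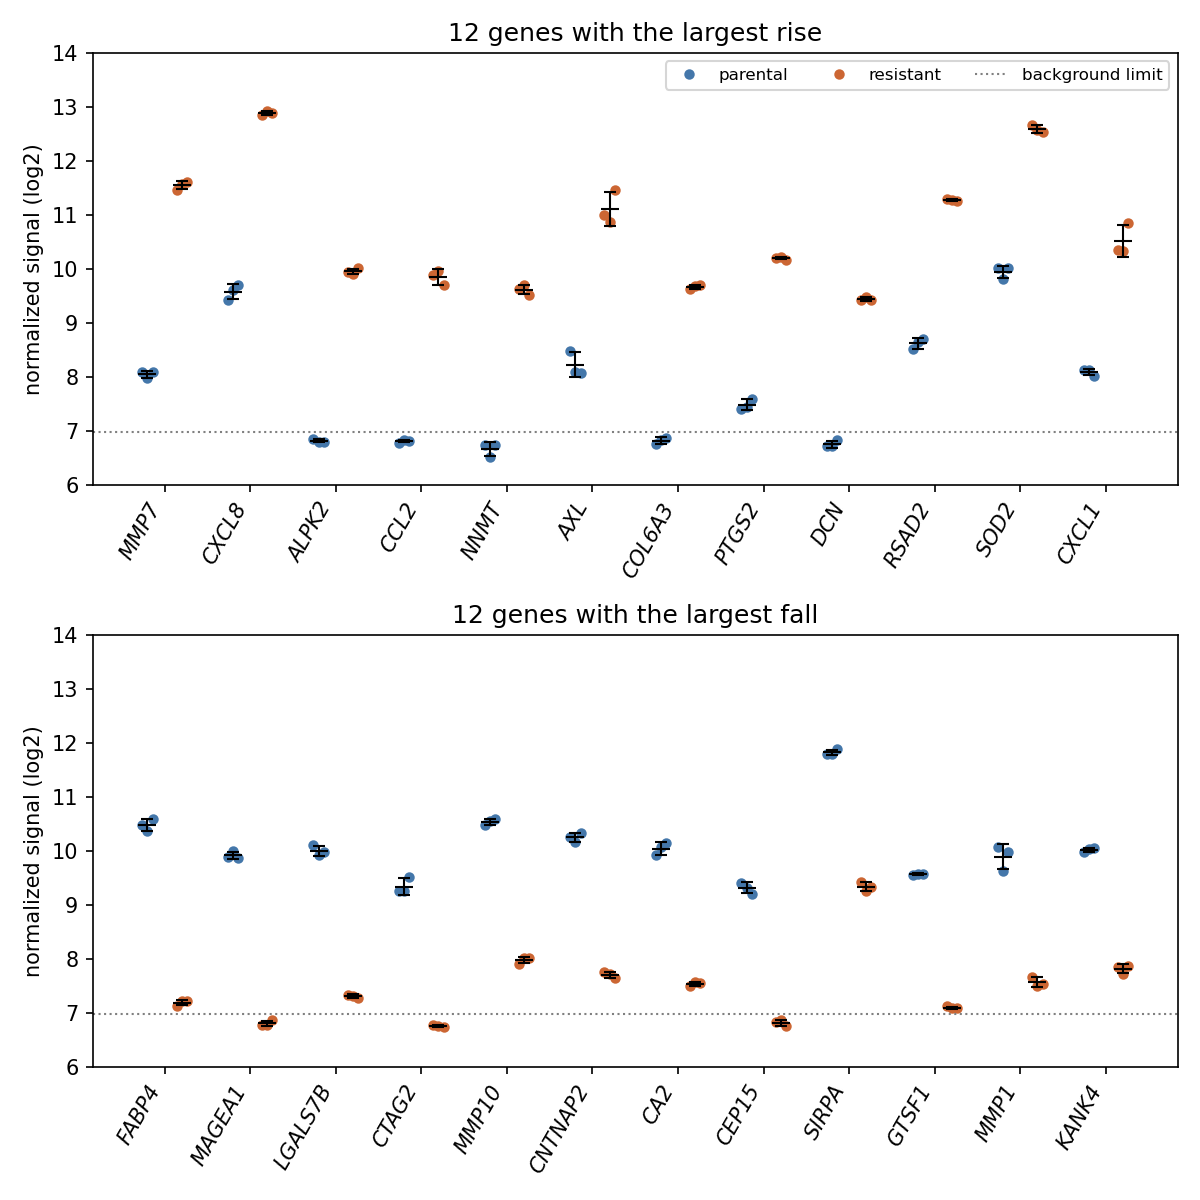
Normalized log2 signal of the 12 genes with the largest measured rise and the 12 with the largest measured fall in 3 parental and 3 resistant arrays; points are arrays, black marks the mean with 1 SD, and the dotted line is the background limit. The groups are apart for each of the 24 genes, and ALPK2, CCL2, NNMT, COL6A3 and DCN lie below the limit on the parental arrays.

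Type I interferon response genes rose together. All 22 tested members were higher in the resistant cells and passed the test, over all genes and adjusted over the list alone, with a median log2 change of 1.23. The list stood apart from other genes (camera adjusted p = 1.98e-17; adjusted p = 0.0448 with an estimated correlation). RSAD2, an antiviral enzyme, rose by 2.66, BST2, the virus-tethering membrane protein tetherin, by 2.30, OASL by 2.16 and IFI27 by 1.84. Several were already bright in parental cells: MX1 went from 13.07 to 13.54 and ISG15 from 12.04 to 13.17. After background subtraction the fold of BST2 went from 4.92 to 8.03. Of the leukocyte markers, CD68 rose by 1.38 (SE 0.0729, limma adjusted p = 4.09e-09), whereas CD14 differed by 0.11 (limma adjusted p = 0.224; 0.0364 without parental replicate 1, and up to 0.603 over the alternatives) and CD79A by -0.07. Those 3 of 8 leukocyte markers were tested, with 1 rising, the same count adjusted over the list alone (camera adjusted p = 0.312). CD68 was already above background on all parental arrays, with a mean of 10.07 there. The fibroblast markers and the endothelial marker PECAM1, given below, rose as well, while the other endothelial markers stayed at background.

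NF-kB and inflammatory cytokine genes were also higher. Of 16 tested, 12 rose and 1 fell (12 and 2 adjusted over the list alone), with a median log2 change of 0.76 (camera adjusted p = 4.98e-06; adjusted p = 0.0448 with an estimated correlation). CXCL8 rose by 3.31 and CXCL1 by 2.43, CCL2 went from background to 9.85, at least 7.35-fold, and IL6 went from background to 7.97, at least 1.99-fold. CCL2, IL6 and CXCL2 passed the filter only through the resistant arrays, so the count of rises follows partly from the filter. The list's mean went from 0.96 to 1.57 with the background mode subtracted. The feedback inhibitors TNFAIP3 and NFKBIA rose by 1.12 and 0.69. IL1B fell by 0.17 (limma adjusted p = 0.0377), and IL1A differed by -0.21 (limma adjusted p = 0.0575). Of the markers of other cell types, CD68, given above, and the fibroblast markers, given below, rose alongside.

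Mesenchymal genes rose. Of 21 listed mesenchymal genes 11 were tested, and 10 of these rose and 0 fell, also adjusted over the list alone, with a median log2 change of 0.74 (camera adjusted p = 4.98e-06; adjusted p = 0.0448 with an estimated correlation). Without the filter, which brings in dim members, the list's mean went from 0.73 to 0.42, and with the background mode subtracted to 1.12; it passed in both. The signalling protein WNT5A went from background to 8.40, at least 2.69-fold, the fibronectin receptor subunit ITGA5 rose by 1.26, N-cadherin (CDH2) by 1.18, the transcription factor TWIST1 by 0.90 and vimentin (VIM) by 0.80. TGFBI differed by -0.04 (limma adjusted p = 0.688). All 4 tested fibroblast markers of 8 rose as well, also adjusted over the list alone (camera adjusted p = 5.25e-04, and 0.0670 with an estimated correlation). DCN, LUM and COL1A2 passed the filter on the probes used only through the resistant arrays, so this count follows partly from the filter. Without the filter the list still passed (camera adjusted p = 2.265e-04), but the genes it was compared with then grew from 11375 to 20046 by adding dim ones. The markers this brought in, COL3A1, FAP, THY1 and PDGFRB, differed by 0.22, 0.14, -0.06 and 0.0018. That pass therefore does not show that the markers rose as a group. The mean of the list went from 1.22 to 0.65 without the filter and to 2.59 with the background mode subtracted. The proteoglycan genes DCN and LUM went from background to 9.45 and 8.22 on their brightest probes, while the dimmest DCN probe reached 6.94, above background on 1 of 3 resistant arrays, and the other LUM probe stayed at background (6.89). COL1A1 rose by 0.55, and COL1A2 went from background to 7.14 on its brighter probe, at least 1.12-fold (1.97-fold with the background mode subtracted). The other COL1A2 probe differed by -0.06 and was above background on all 3 parental arrays (7.03) and on 2 of 3 resistant arrays (6.97). By that probe COL1A2 was not at background in parental cells. The mean of its probes lost the call (adjusted p = 0.116, and 1.62e-04 to 0.116 over the alternatives). The endothelial marker PECAM1, the only one of 7 tested, went from background to 7.26, at least 1.22-fold, and passed, also adjusted over the list alone (2.73-fold with the background mode subtracted). It passed the filter only through the resistant arrays. The other endothelial markers, VWF, CDH5, KDR, TEK, CLDN5 and ESAM, were at background on all arrays of both groups.

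Among 16 epithelial junction and identity genes, 12 fell and 2 rose, the same counts adjusted over the list alone, with a median log2 change of -0.42 (camera adjusted p = 5.25e-04; adjusted p = 0.203 with an estimated correlation). The list's mean went from -0.40 to -0.63 with the background mode subtracted. E-cadherin (CDH1) fell by 0.95, the tight junction gene CLDN1 by 0.85 and the desmosomal gene DSP by 0.94, and RAB25 fell to background, at least 2.11-fold. KRT8, a keratin of simple epithelia, went the other way, from background to 7.65, at least 1.59-fold, and its partner KRT18 rose by 0.15. Fibroblast markers, given with the mesenchymal genes, rose between the same groups, and a link to these falls was not tested. Of 10 basal keratinocyte genes 7 fell and 0 rose, also adjusted over the list alone (median -0.41, camera adjusted p = 0.00211; adjusted p = 0.246 with an estimated correlation). P-cadherin (CDH3) fell by 1.34, and the basal keratins KRT5, KRT15 and KRT14 fell by 1.11, 0.60 and 0.53. Keratinocyte differentiation genes went both ways, with 3 of 14 rising and 6 falling (4 and 6 adjusted over the list alone, camera adjusted p = 0.312). CALML3 fell by 1.19, the protease KLK5 by 1.13 and KRT13 by 0.88, whereas the cornified envelope gene SPRR2D rose at least 1.98-fold from background. With the background mode subtracted the folds of KRT13 and KLK5 went from 1.84 and 2.19 to 3.74 and 3.38.

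ERK output genes, transcripts induced by MAP kinase signalling downstream of EGFR, were mostly higher in the resistant cells. Of 17 tested 11 rose and 2 fell (13 and 2 adjusted over the list alone), with a median log2 change of 0.44 (camera adjusted p = 4.26e-04; adjusted p = 0.0670 with an estimated correlation). The transcription factor ETV5 rose by 1.59, FOSL1 by 1.22 and the early response gene IER3 by 0.86. The feedback inhibitors SPRY2 and DUSP6 rose by 1.49 and 0.44. EGR1, an immediate early transcription factor, fell by 1.10, and SPRED2 fell by 0.25. Fibroblast markers rose between the same groups here too, and a link to these genes was not tested.

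Cell cycle genes were lower. Of 24 tested 17 fell and 1, AURKA, rose by 0.25, the same counts adjusted over the list alone (median -0.32, camera adjusted p = 1.13e-04; adjusted p = 0.0670 with an estimated correlation). All 6 tested subunits of the MCM replicative helicase fell, with MCM6 at -0.71, MCM2 at -0.69, MCM5 at -0.61, MCM7 at -0.57, MCM4 at -0.52 and MCM3 at -0.32. The proliferation marker MKI67 differed by -0.15 (limma adjusted p = 0.128). CD68 and the fibroblast markers, given above, rose between the same groups.

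Of 15 hypoxia and glycolysis genes 10 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.32, camera adjusted p = 0.00283; adjusted p = 0.0751 with an estimated correlation). The mitophagy receptor BNIP3 rose by 1.62, ANGPTL4 by 0.82, NDRG1 by 0.52 and VEGFA by 0.49, while the glucose transporter SLC2A1 fell by 0.35. With the background mode subtracted the fold of ANGPTL4 went from 1.76 to 3.10. Of 12 YAP target genes, a list that includes AXL, 7 rose and 1 fell, the same counts adjusted over the list alone (median 0.23, camera adjusted p = 0.00430; adjusted p = 0.0797 with an estimated correlation). CCN2, a matricellular protein, rose by 1.91, ASAP1 by 1.21 and the ectonucleotidase NT5E by 1.08, and AJUBA fell by 0.47. Fibroblast markers, given with the mesenchymal genes, rose alongside these lists as well.

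The remaining lists did not pass as lists, although single members changed. Of 14 cholesterol synthesis genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0635). INSIG1 rose by 0.82, HMGCS1 by 0.44, LSS by 0.36 and SQLE by 0.34; the list passed without the filter on dim probes (adjusted p = 0.0132) and with the mean of a gene's probes (0.0490), and the alternatives, fry included, spanned 1.33e-04 to 0.196. Of 14 NRF2 target genes 5 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.749), with TXNRD1 up by 0.75 and AKR1C3 at -0.66. Of 8 genes of xenobiotic metabolism and drug transport 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.380). The transporter ABCC3 rose by 0.93 and the aryl hydrocarbon receptor targets CYP1B1 and TIPARP by 0.77 and 0.54, while CYP1A1 fell by 0.39, a fold of 1.31 that background subtraction raised to 1.98. Among 11 BCL2 family genes 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.312): the pro-apoptotic genes PMAIP1 and BID rose by 1.88 and 0.63, and the anti-apoptotic gene BCL2L1 rose by 0.41. Stress response genes of the ATF4 and unfolded protein pathways were split, with 6 of 12 rising and 4 falling, the same counts adjusted over the list alone (camera adjusted p = 0.539). ATF3 rose by 0.70, XBP1 by 0.55 and PHGDH by 0.48, whereas the amino acid transporter SLC7A5 fell by 1.57. Altogether 10 of the 20 lists tested passed with the preset correlation, 7 higher, the fibroblast markers among them, and 3 lower. Of these 10, the 3 lists of interferon, NF-kB and mesenchymal genes passed with an estimated correlation.

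**Figure D3:**
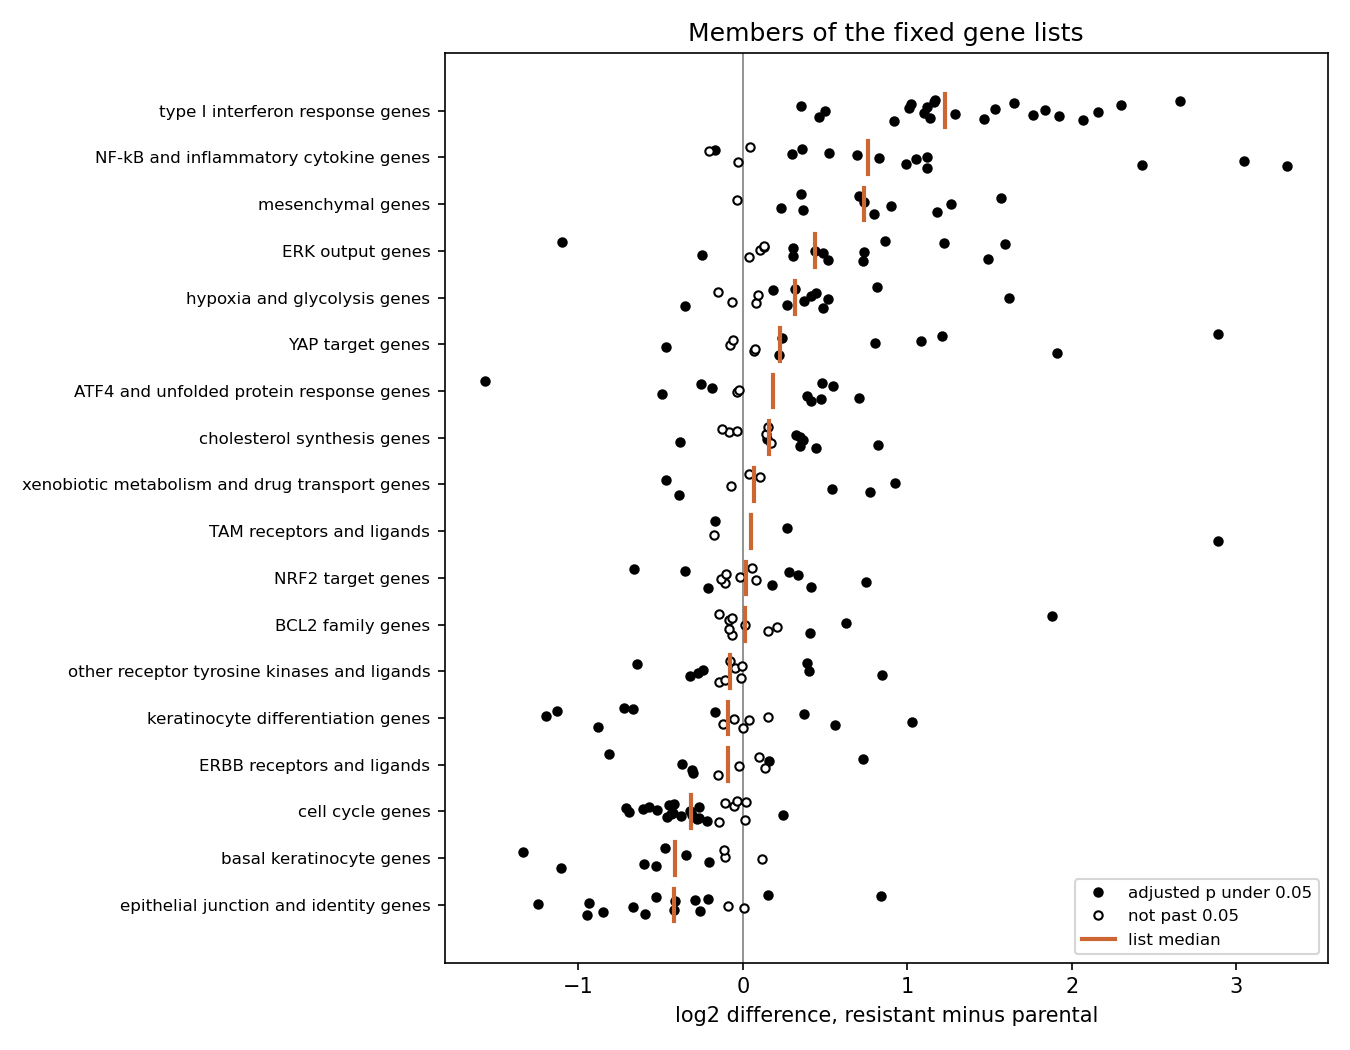
Log2 difference between resistant and parental cells for each tested member of the fixed gene lists, without the markers of other cell types; filled points passed an adjusted p of 0.05, open points did not, and orange bars are list medians. All 22 interferon response genes lie above 0, and the medians of the epithelial, basal keratinocyte and cell cycle lists lie at -0.42, -0.41 and -0.32.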

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

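The strict filter, cyclic loess and background subtraction were chosen only after the data were seen. AXL kept its direction and call in all alternatives, and counts of genes and lists stayed within 1.5 times except as follows. With the background mode subtracted, 1006 genes changed at least 2-fold (610 rose, 396 fell) against 362 (227 and 135), which follows from its construction, since it stretches values near the floor. A test against a fold of 1.2 called 2008 genes, which follows from its lower limit. Camera passed 3 lists with an estimated correlation, against 10. For the ERK, hypoxia, YAP and fibroblast lists the estimate was below the preset 0.01 (-0.0119, -0.0418, -0.0535 and -0.0824), so a higher correlation did not cost these calls. For the epithelial, basal keratinocyte and cell cycle lists it was above (0.173, 0.276 and 0.0252). Whether the higher correlation cost those calls cannot be read from this, since lists with a lower estimate lost theirs too. Fry, which does not compare a list with other genes, passed 18 for direction and 20 for change in either direction. In the other settings, leave-one-out included, camera passed 10 or 11 lists. Genes changed ranged from 5427 to 5646 when 1 array was left out, from 353 to 370 at least 2-fold, and AXL from 2.71 to 3.02. Of the 6029 genes 5301 to 5450 were still called then, 0 with the opposite sign; 10 had it with the mean of probes, 1 without the filter and 0 in the other settings. Genes changed numbered 6081 without a filter, 5836 with the strict filter, 6108 with the mean of probes, 6116 with trend and robust, 6064 with array weights, 6035 with cyclic loess (51.6% rising against 49.2%), 5750 with background subtracted and 4709 at an adjusted p under 0.01. With the replicate block they numbered 6135, and 10 lists passed. The deviations of same-numbered parental and resistant arrays correlated at 0.144, 0.00181 and 0.0855, and not every array correlated best with its own number, so the numbers were not taken to pair samples. Over named genes and lists, the direction (camera's, for lists) and side of the threshold were kept in 1345 and 302 comparisons with an alternative, while calls were gained in 15 and 10 and lost in 10 and 7; causes were not tested. EGFR alone turned, from -0.154 to 0.0548 with the mean of its probes, and passed in neither. Not run, because no raw column could be tied to a sample: normexp of raw signals, its offset of 50, no background correction, scaling to an upper percentile and detection p filters. With the mode subtracted, 5426 of the 6029 calls were kept. Signal near background limits what can be said of dim genes, but whether the lost calls were of dim genes was not tested.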

Other observations

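The gene families in this part, and the tests for fibroblasts, leukocytes and probe brightness, were chosen only after the results were seen. Genes of antigen presentation rose with the interferon response genes: of 22 tested HLA and antigen processing genes 18 rose and 0 fell (camera adjusted p = 2.00e-06 over 8 families; adjusted p = 0.0748 with an estimated correlation). HLA-B rose by 0.93 and TAP1 by 0.64, and the class II gene HLA-DPA1 went from background to 8.27; probes of HLA genes can bind related copies. Of 6 guanylate-binding protein genes 5 rose, led by GBP2 at 2.12, and GBP6 fell by 1.04 (camera adjusted p = 0.00213; adjusted p = 0.0748 with an estimated correlation). Of 19 chemokine genes 14 rose and 1 fell (camera adjusted p = 2.00e-06; adjusted p = 0.0437 with an estimated correlation). CCL2, CCL3, CCL3L1, CCL3L3, CXCL2 and CXCL6 passed the filter only through the resistant arrays, so this count follows partly from the filter. CCL3, CCL3L1 and CCL3L3 rose at least 1.07-fold, 1.03-fold and 1.13-fold. The interferon-induced chemokine CXCL10 rose by 2.35 and CXCL6 rose at least 3.65-fold from background, while CXCL14 fell by 0.96; this family shares 7 tested members with the NF-kB list. IDO1 and TDO2 encode enzymes that start tryptophan breakdown; IDO1 rose at least 4.90-fold from background and TDO2 rose by 2.39 (limma adjusted p = 3.79e-12 and 4.03e-12). CD68 rose and other leukocyte markers did not pass, as given with the interferon list, and fibroblast markers rose, as given with the mesenchymal genes.

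Collagen genes went both ways. Of 24 tested chains 10 rose and 8 fell (camera adjusted p = 0.480). COL13A1, COL15A1, COL1A2, COL24A1, COL6A2 and COL6A3 passed the filter only through the resistant arrays, so the count of rises follows partly from the filter. COL6A1 rose by 2.42, COL6A2 and COL6A3 went from background up at least 2.63-fold and 6.47-fold, and COL5A1 rose by 0.74. COL5A2 fell by 1.87 and COL4A6 by 1.10, COL22A1 fell to background, at least 2.37-fold, and COL4A1 was at 0.00; the fibroblast markers DCN and LUM rose alongside. Matrix metalloproteinases also went both ways, with 2 of 10 rising and 3 falling (camera adjusted p = 0.190). Of 6 metallothionein genes, which encode metal-binding proteins and are close copies, 4 fell and 0 rose, with MT1F at -2.14 and MT1E at -1.24 (camera adjusted p = 0.00213; adjusted p = 0.0748 with an estimated correlation). Of 11 cancer-testis antigen genes 4 fell and 1 rose (camera adjusted p = 0.0235; adjusted p = 0.0900 with an estimated correlation). MAGEA1, CTAG2 and CTAG1A reached background, while MAGEA6 and MAGEA3 differed by -0.06 and 0.13. Replication-dependent histone genes rose in 11 of 26, led by H2BC5 at 1.05, and fell in 1 (camera adjusted p = 0.0178, and 0.0752 with an estimated correlation). The gene that fell, H4C3 at -0.25, was the brightest of them. Which histone transcripts the probes read after this labelling was not tested, so these counts are no measure of replication.

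The interferon response was weighed first. RNA of leukocytes in the resistant cultures is argued against as its source: of the 7 fixed leukocyte markers with a probe 1, CD68, was above background on all resistant arrays and rose, and all 4 probes of the pan-leukocyte gene PTPRC were at background. A distortion that depends on probe brightness is also argued against: the list's median was 1.231, while 10000 random lists matched on signal had a central 95% range of -0.171 to 0.142 and reached 0.347 at most. The leukocyte and brightness tests were written after the rise of the list and of CD68 had been seen, so neither was a prediction. A candidate explanation is interferon made by the resistant cells: 3 of 9 interferon genes, IFNB1, IFNL1 and IFNL2, rose from background to just above it (7.34, 7.18 and 7.05). The other IFNL1 probe and IFNL3 stayed at background (6.95 and 6.93), and IFNE fell by 0.33. The rule asked for at least 1 of the 9 to rise, and 2967 of all 11375 tested genes rose. The 3 genes were tested only through the resistant arrays, so the rule was easily met and gives weak support. Erlotinib in the medium, resistance itself and culture history were not tested and stay open.

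The fibroblast markers could come from fibroblasts in the resistant cultures or from the carcinoma cells themselves. Of 4 transcripts that fibroblasts hold in abundance, COL1A1, COL1A2, COL3A1 and SPARC, 2 were above background on all resistant arrays and rose. COL1A2 counts only by its brighter probe, as given with the mesenchymal genes, and by its other probe only COL1A1 would count. SPARC stayed at background (6.86), as did the markers THY1 (6.69) and PDGFRB (6.79), and COL3A1 and the marker FAP were above it on 2 of 3 resistant arrays. Levels of different probes cannot be set against each other, so fibroblasts and a change in the carcinoma cells cannot be told apart here.

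The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split gave 6029 changed genes, 362 changed at least 2-fold and 10 lists, and was the 1 split of the 10 to reach each count. The highest of the others gave 0, 0 and 9. Each other split mixes parental with resistant arrays, so the difference between the groups adds to the spread within them. Low counts there follow from a large difference and do not measure what chance would give.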
